A study of Xenopus laevis with 12 samples.

How the data were processed

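RNA was extracted from dissected rhombomere 1 of Xenopus laevis tadpoles with Trizol, and libraries were made with a stranded mRNA ligation kit, per the labels' protocols. The design text states paired-end sequencing on an Illumina NovaSeq. It gives stage 42 and 3 replicates per condition with 3 rhombomeres each, whereas the labels give stage 41 and 4 samples per group. The labels were followed, and they do not say whether the 4 samples of a group came from separate embryos. The group of each library was taken from its treatment label and its replicate number from its title.

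The deposited files hold raw counts, whole numbers per gene ID, with 1 library per file and no normalization. The counts were made by the authors with featureCounts 2.0.1, per the submitters' processing notes, from reads that had been trimmed, per the file headers. The genotype label reads Xenla9.2, which resembles the name of a genome build, while most gene IDs start with XBXL10, and which build was used for alignment and counting is not settled by the labels or the files. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, it cannot be told whether reads of overlapping or antisense genes were credited to the right gene. Whatever that setting, reads shared by near-identical copies, such as the homeologs of this allotetraploid species, can be credited to the wrong gene. Each file lists 44478 gene IDs, of which 44453 start with XBXL10_1g, 24 with XBmRNA, and 1 has another form. No row lacked a gene ID. The RefSeq gene table at hand (assembly Xenopus_laevis_v10.1, 44456 genes) matched 0 of the IDs by exact comparison. The files do not pair IDs with names, so the tests of gene lists fixed before the data were examined, the list of Wnt and T-cell factor targets, the barhl1 transcript and the sum of homeologs were not run. For the same reason the targeted gene could not serve as a check of the labels.

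The total count per library was 23278184 to 29433422, and the genes tested held 99.9% of the counts in each. Before groups were averaged, pairs of libraries within a group were compared by chi-square over genes, which gave 6.41 to 28.9 per degree of freedom, so none was a copy of another within sampling noise. Across groups the lowest values of all pairs were 4.32 for control replicate 1 with MO2 replicate 1, which also had the highest Spearman correlation of all pairs (0.994), and 5.05 for control replicate 1 with MO1 replicate 2.

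Genes were kept by filterByExpr on the groups, which left 26712. Counts were scaled by TMM, and all 12 libraries were fitted in 1 edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3, robust dispersion, 9 residual degrees of freedom) with a coefficient per group. The common biological coefficient of variation was 0.173. The contrasts were each morpholino against the control, the mean of both against the control, and MO1 against MO2, all two-sided. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors were taken from the fold change and the test statistic. CPM values are TMM-scaled, and principal components used log2 CPM with a prior count of 2. The tests and comparisons of these contrasts and the rule for named items were fixed before the data were examined, and each part of the closing section names the tests chosen later. The rule took IDs past the threshold in the mean comparison, with the same sign for both morpholinos and a mean CPM of at least 2, by size of the fold change. At most 2 per direction are printed, fewer than the rule allowed, since no names are paired. The rule also had a part for each single morpholino and for MO1 against MO2, which was not applied. The IDs of the mean comparison are given there instead, so other IDs that passed with MO2 are not shown.

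Tested on simulated data with 200 changed genes among 26712, the mean comparison recovered 85% of 2-fold and 57% of 1.5-fold changes and called 6 unchanged genes. The MO1 comparison recovered 79% and 45%, and the MO2 comparison 76% and 44%. The changed genes were drawn from those with a mean CPM of at least 1. The simulated libraries held no structure beyond their groups, so these shares need not hold for the real libraries. Both comparisons share the controls, so 20 simulations of unchanged groups and controls, drawn from the real means, library sizes and dispersions with genes independent of each other, gave the values of chance agreement (with all 12 libraries, and with the 11 left without control replicate 1), and the 4 controls were also split 2 and 2 in all 6 ways.

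The alternatives fixed before the data were examined were DESeq2 size factors within edgeR, no filter on low counts, a stricter filter (CPM of at least 1 in 4 libraries), DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, only the groups compared in the fit, a minimum log2 fold change of 1, and leaving out each library in turn. Alternatives chosen after seeing the data were both morpholinos as 1 group of 8, library quality weights in limma-voom, and 1 or 2 surrogate variables (sva 3.50.0). DESeq2 gave no adjusted p for 1568 genes of the mean comparison, which were not counted as called.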

Results

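Gene expression was measured by RNA sequencing in rhombomere 1, the anterior hindbrain segment from which the cerebellum forms, of Xenopus laevis tadpoles at stage 41 per the sample labels. Embryos had received a control morpholino or 1 of 2 morpholinos against barhl1, called MO1 and MO2 here. Morpholinos are antisense oligonucleotides that block translation or splicing of their target RNA. barhl1 encodes a homeodomain transcription factor, which the submitters describe as acting downstream of Atoh1 and as inhibiting T-cell factors. Each of the 3 groups held 4 libraries. The total count per library ran from 23278184 in control replicate 1 to 29433422 in MO2 replicate 4. Between 32094 and 32960 gene IDs had at least 1 count in a library. The files do not pair these IDs with gene names, so the level of barhl1 itself, its relatives and the named gene groups are not reported, and at most 2 IDs per direction are printed. Replicate error below is the spread between these libraries, and p-values measure that spread only.

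The groups were not fully separated by overall expression. The first principal component of the log2 CPM values held 28.3% of the variance and the second 22.1%. Control replicates 2, 3 and 4 had negative scores on both components, as did MO1 replicate 3 at -9.35 and -9.96. Control replicate 1 scored 6.73 on the first and -7.79 on the second, beside MO2 replicate 1 at 5.15 and -6.86. MO2 replicates 3 and 4 stood apart on the second component, with scores of 64.3 and 48.7. The mean Spearman correlation of control replicate 1 was 0.987 with the other controls and 0.989 with the 8 morpholino libraries. That of MO1 replicate 3 was 0.989 with the controls and 0.986 with the other morpholino libraries.

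**Figure D1:**
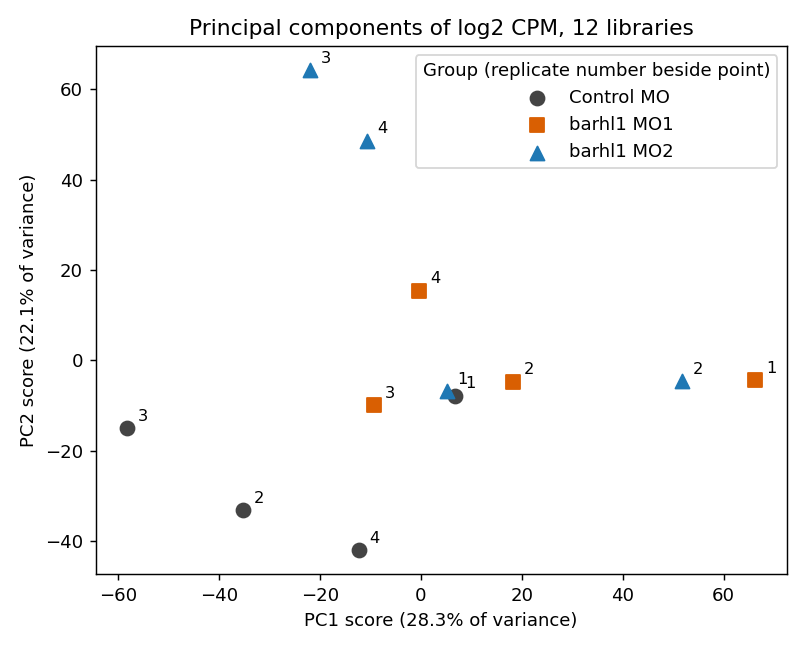
Scores of the 12 libraries on the first (28.3% of variance, horizontal) and second (22.1%, vertical) principal component of log2 CPM, with symbols for the 3 groups and the replicate number beside each point. Control replicate 1 (6.73 and -7.79) lies beside MO2 replicate 1 (5.15 and -6.86), away from the other 3 controls.

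The effect of barhl1 depletion was first tested as the mean of both morpholinos against the control. XBXL10_1g15791 rose from 1.15 ± 0.492 CPM in the control to 3.48 ± 0.506 with MO1 and 3.77 ± 1.06 with MO2 (SD, n = 4 each), a log2 fold change of 1.66 (SE 0.25, edgeR adjusted p = 0.0392). XBXL10_1g35344 rose from 2.55 ± 0.705 to 6.90 ± 2.02 and 7.04 ± 1.87 CPM, a log2 fold change of 1.46 (SE 0.23, edgeR adjusted p = 0.0469). In the other direction, XBXL10_1g9012 went from 9.42 ± 2.61 CPM to 4.80 ± 0.735 with MO1 and 4.54 ± 0.522 with MO2, a log2 fold change of -1.02 (SE 0.15, edgeR adjusted p = 0.0392). XBXL10_1g31540 went from 8.64 ± 1.69 CPM to 5.27 ± 0.921 and 3.65 ± 0.607, a log2 fold change of -0.98 (SE 0.15, edgeR adjusted p = 0.0392). For XBXL10_1g15791 and XBXL10_1g35344, all 8 morpholino libraries lay above all 4 controls, and for XBXL10_1g9012 all 8 lay below them. For XBXL10_1g31540, 7 of the 8 lay below all 4 controls. The 4 IDs were chosen by threshold and fold change in these same libraries, which favors such separation, so it is no separate support.

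**Figure D2:**
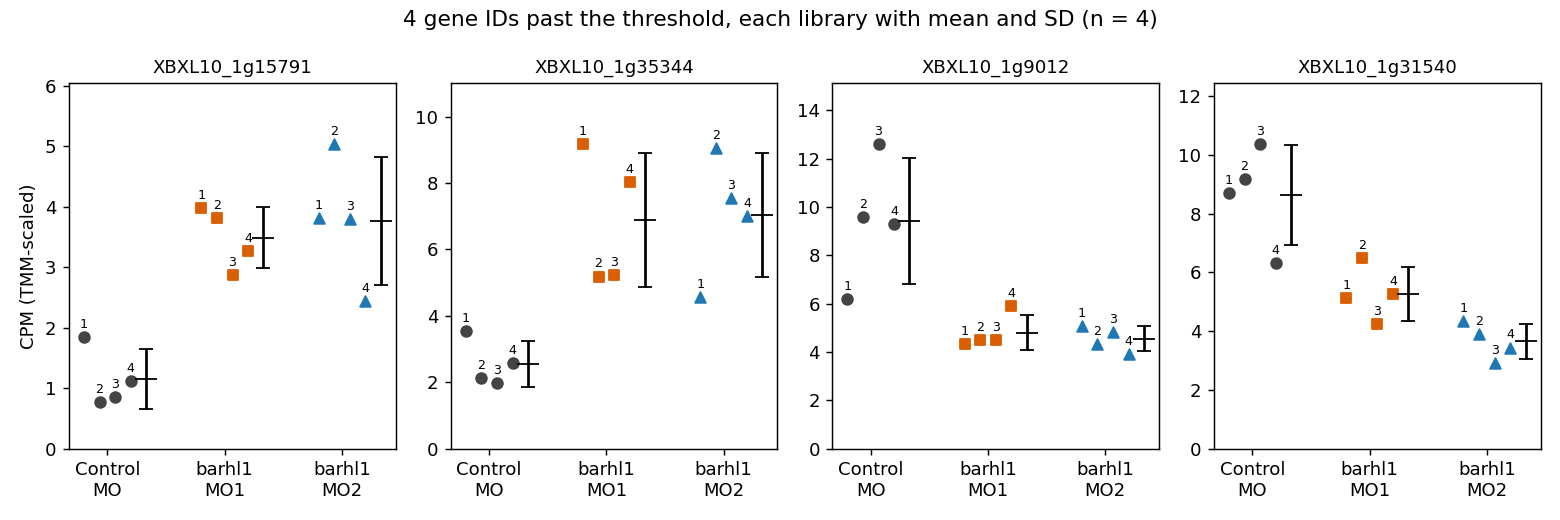
TMM-scaled CPM (vertical) in each library (points, with replicate number) of 4 gene IDs past the threshold in the comparison of the mean of both morpholinos with the control, and the group mean with SD (bars, n = 4). Group means for control, MO1 and MO2 were 1.15, 3.48 and 3.77 for XBXL10_1g15791, 2.55, 6.90 and 7.04 for XBXL10_1g35344, 9.42, 4.80 and 4.54 for XBXL10_1g9012, and 8.64, 5.27 and 3.65 for XBXL10_1g31540.

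These IDs are among 9 that passed an adjusted p of 0.05 in this comparison (edgeR quasi-likelihood test, 26712 genes tested), of which 4 rose and 5 fell. All 9 had the same sign with MO1 and with MO2, which their selection on the mean of both against the same controls makes likely. At an unadjusted p under 0.05 there were 5635 genes, 21.1% of those tested, where 1335.6 would be expected if nothing differed. This count was 3152 without control replicate 3 and 3291 without control replicate 4, and, under alternatives chosen after seeing the data, 640 with 2 surrogate variables in the fit and 9492 with library quality weights. The number of calls depended on control replicate 1, without which 2669 genes passed, 1371 higher and 1298 lower, with all 9 of the first set among them. Of the controls, this one was the most like the morpholino libraries, so leaving it out favors more calls. The 9 were called with the libraries that remain, so their return is no independent support. The same limit applies to the results without control replicate 1 given below. The number of calls was 0 without control replicate 2, control replicate 3 or MO2 replicate 3. It was 1 without control replicate 4 or MO1 replicate 1, 4 without MO1 replicate 2 or MO2 replicate 2, 5 without MO2 replicate 4, 18 without MO1 replicate 3 and 93 without MO2 replicate 1. DESeq2 called 1417 genes, 801 higher and 616 lower, and limma-voom called 0, or 4617 with library quality weights. Without a filter on low counts edgeR called 30, and with 2 surrogate variables or with the replicate number as a block 0.

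With MO1 alone, XBXL10_1g15791 had a log2 fold change of 1.61 (SE 0.28) and XBXL10_1g35344 one of 1.44 (SE 0.25) against the control. XBXL10_1g9012 and XBXL10_1g31540 had log2 fold changes of -0.98 (SE 0.18) and -0.71 (SE 0.17). None of these 4 passed in this comparison, with edgeR adjusted p of 0.112 for the first 3 and 0.169 for XBXL10_1g31540. No gene passed, the smallest edgeR adjusted p being 0.112, whereas 4025 genes (15.1%) had an unadjusted p under 0.05. That number was 6510 without control replicate 1, 2196 without control replicate 3, 2520 without control replicate 4, 1034 with 2 surrogate variables and 8005 with library quality weights. DESeq2 called 402 genes and limma-voom 0, or 1813 with library quality weights. Without control replicate 1, edgeR called 544 genes, 236 higher and 308 lower, and among these XBXL10_1g15791, XBXL10_1g35344 and XBXL10_1g9012 had adjusted p of 0.00643, 0.0131 and 0.00643. Without MO1 replicate 4 edgeR called 6 genes.

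With MO2 alone, XBXL10_1g31540 had a log2 fold change of -1.24 (SE 0.18, edgeR adjusted p = 0.0355) against the control. XBXL10_1g15791, XBXL10_1g35344 and XBXL10_1g9012 had log2 fold changes of 1.72 (SE 0.28), 1.47 (SE 0.25) and -1.05 (SE 0.18), with edgeR adjusted p of 0.0819, 0.0952 and 0.0952. In all, 3 genes passed, 1 higher and 2 lower, and 5502 (20.6%) had an unadjusted p under 0.05. The latter number was 3632 without control replicate 3, 3400 without control replicate 4, 3564 without MO2 replicate 3 and 566 with 2 surrogate variables. DESeq2 called 1154 genes and limma-voom 0, or 1419 with library quality weights. edgeR called 6 without a filter on low counts, 67 with 1 surrogate variable, and 0 with 2 or with the replicate number as a block. Without control replicate 1, edgeR called 1992 genes, 1116 higher and 876 lower, and without MO2 replicate 1 it called 58. It called 1 without control replicate 4, and 0 without control replicate 2 or 3, MO1 replicate 1, 3 or 4, or MO2 replicate 2, 3 or 4.

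**Figure D3:**
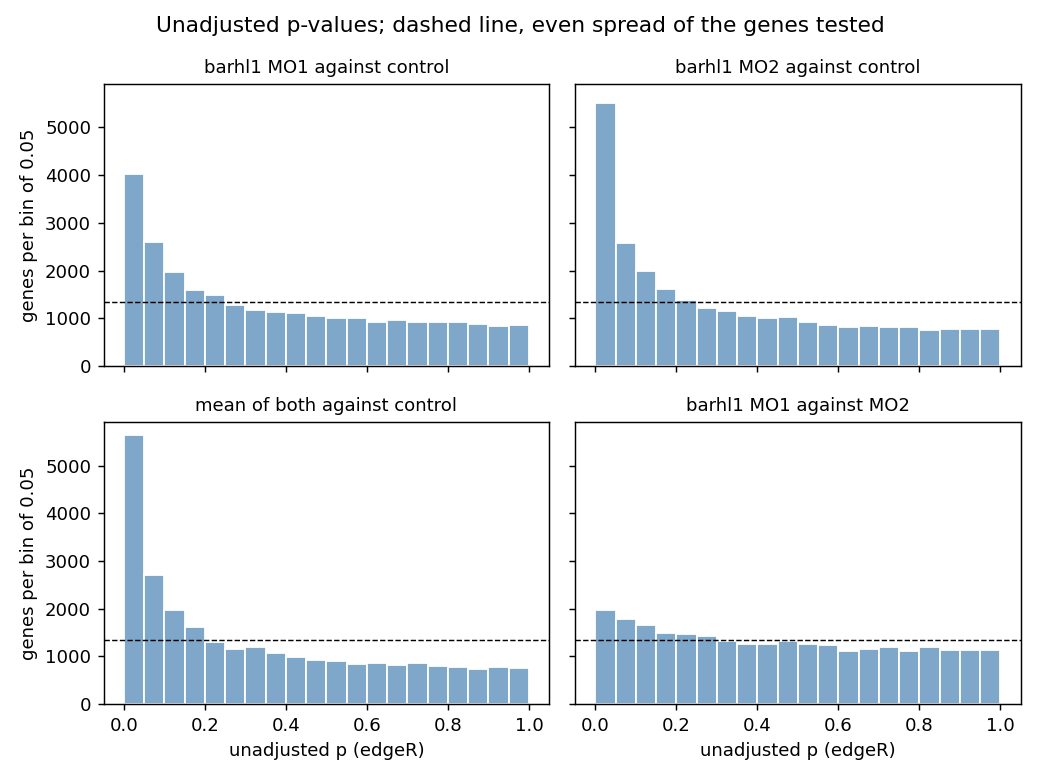
Number of genes (vertical) per bin of 0.05 of the unadjusted edgeR p (horizontal) in the 4 comparisons, with a dashed line at an even spread of the genes tested, 1335.6 per bin. The first bin holds 4025 genes for MO1, 5502 for MO2, 5635 for the mean of both and 1964 for MO1 against MO2.

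The direct comparison of MO1 with MO2 asked whether an effect was seen with 1 morpholino only. XBXL10_1g31540 was at 5.27 ± 0.921 CPM with MO1 and 3.65 ± 0.607 with MO2, a log2 difference of 0.53 (SE 0.18, edgeR adjusted p = 0.649). XBXL10_1g15791, XBXL10_1g35344 and XBXL10_1g9012 differed by -0.11 (SE 0.26), -0.03 (SE 0.24) and 0.08 (SE 0.19) on the log2 scale, none past the threshold. No gene passed in edgeR, and 1964 genes (7.35%) had an unadjusted p under 0.05. That number was 3446 without MO2 replicate 2, 1247 without MO2 replicate 3 and 1014 without MO2 replicate 4. DESeq2 called 11 genes and limma-voom 0. Without MO2 replicate 1 or MO2 replicate 2 edgeR called 1 gene.

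Many genes differed from the shared controls in the same direction in both morpholino groups. At an unadjusted p under 0.05 in both comparisons, 1127 genes were higher with both and 905 lower with both. Independent lists of these lengths would share 229.7 and 185.6, which leaves out the shared controls. Simulated unchanged groups that shared 1 set of simulated controls had 142.8 and 115.2 in common. Their lists were shorter, with 1225 genes at this p in the mean comparison against 5635 in the real data. The simulated values are thus not the overlap that shared controls give at the real list lengths, which was not estimated. Of the other genes at this p in both, 0 were higher with MO1 and lower with MO2, and 1 was lower with MO1 and higher with MO2. Shared controls also lower the number in opposite directions, and with the controls split so that each morpholino had its own pair, 214 to 364 genes were higher with both, 194 to 275 lower with both and 9 to 50 in opposite directions over the 6 splits. Across genes, which are not independent replicates, the log2 fold changes of both morpholinos had a Pearson correlation of 0.739, against 0.501 in the simulation, and a covariance of 0.132 against 0.0401, a difference of 0.0923. In these splits the correlation was 0.379 to 0.554 and the covariance 0.0898 to 0.118. At the adjusted threshold 0 genes passed in both comparisons with edgeR, 0 with limma-voom (598 with library quality weights) and 175 with DESeq2. Without control replicate 1, 404 passed with edgeR, 189 higher with both and 215 lower with both, and 0 in opposite directions. Independent lists would share 9.73 and 9.96, a value that leaves out the shared controls, and simulated unchanged groups with shared controls had 0.05 and 0 in common on average. The simulation allows neither for the choice of the library left out nor for structure among the libraries, so it does not exclude chance.

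**Figure D4:**
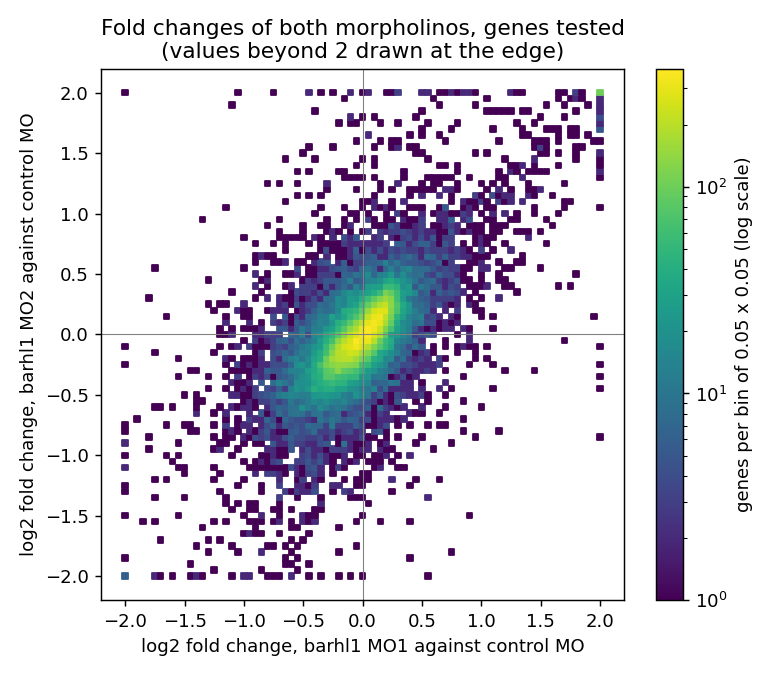
Log2 fold change against the control with MO1 (horizontal) and with MO2 (vertical), the color giving the number of genes per bin of 0.05 on a log scale. The Pearson correlation across genes was 0.739, and the 211 genes beyond 2 on either axis are drawn at the edge.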

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

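The tests of an exchange of control replicate 1 with MO1 replicate 3 or with another single library, and the positions on genes of small fold change, were chosen after the results were seen, and the other tests of this part were set before their outcome. Over 39 sets of 4 libraries (13 measures in 3 groups), 3 held a library far from the rest of its group, where chance gives about 1 in 20, or 1.95. In MO1 replicate 3 the 10 most abundant genes took 3.92% of counts, against 4.37% to 4.45% in the other MO1 libraries, 3.70% to 3.97% in control replicates 2 to 4, 4.28% in control replicate 1 and 3.90% in MO2 replicate 2. In MO1 replicate 4, XBXL10_1g9012 was at 5.89 CPM, against 4.32 to 4.50 in the other MO1 libraries and 9.42 ± 2.61 in the control (SD, n = 4). Control replicate 1 stood apart in its position between controls and morpholino libraries.

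That position was measured on the 500 genes with the smallest p when the library itself was left out, with 0 at the mean of the other controls and 1 at the mean of the morpholino libraries. Control replicate 1 was at 0.804, the other controls at -0.00312 to 0.133, and the morpholino libraries at 0.491 to 1.27. Its lower depth is argued against, since with all libraries thinned to 1 total it was at 0.790 and the other controls at no more than 0.119. Its 0.804 lies inside the morpholino range, but control replicate 1 helped to set the axes of that range. On axes from other libraries, chosen later, it was at 0.727 to 0.828 on 500 such genes. The 7 morpholino libraries other than MO1 replicate 3 were at 0.736 to 1.08. It was below each of these held out with it, but above MO2 replicate 1 on all genes at an unadjusted p under 0.05 (0.623 against 0.614). What stays open is that control replicate 1 may be a single mislabelled library, or that tadpoles or dissections of the control group differed this much. The latter was not tested.

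Whether the labels of control replicate 1 and a morpholino library were exchanged was tested by the lowest morpholino position, 0.491, which lies above the bound set in advance, the highest of the other controls at 0.133. That bound was too weak, since control replicate 1 itself helped to choose the genes and set the 0 of that axis. With genes and axis from other libraries, the 7 morpholino libraries other than MO1 replicate 3 were at 0.614 or more on all genes at an unadjusted p under 0.05, against 0.149 to 0.278 for control replicates 2 to 4, which argues against an exchange with any of these. For MO1 replicate 3 the exchange cannot be told apart from correct labels: it was at 0.694 to 0.777 on the 500 genes with the smallest p (control replicates 2 to 4 at 0.00737 to 0.237) and at 0.549 to 0.638 on all genes at that unadjusted p, both clear of these controls, but on those of them with a log2 fold change under 1 it was at 0.419 to 0.485, nearer to control replicates 2 to 4 (0.0907 to 0.274) than to the other morpholino libraries (0.755 to 1.13), while control replicate 1 was at 0.760 to 0.839.

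Admixture of morpholino RNA in control replicate 1 cannot be told apart from these. On 19 genes with no count in control replicates 2 to 4 and counts in all 8 morpholino libraries, control replicate 1 was at 0.137 of the morpholino mean. That is under the bound of 0.268 set in advance, but the bound was wrong, since MO2 replicate 1 and MO1 replicate 3 themselves were at 0.162 and 0.200 of the mean of the other morpholino libraries on such genes.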

How the results depend on the processing

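Library quality weights, surrogate variables and the morpholinos as 1 group of 8 were chosen after seeing the data, and the other alternatives before. Counts are given for MO1 against control, MO2 against control, the mean of both, MO1 against MO2, and both morpholinos in the same direction, with 0, 3, 9, 0 and 0 as reported. DESeq2 called 402, 1154, 1417, 11 and 175, and limma-voom 0 for MO2 and for the mean. Among 20 groupings of the libraries only the real one, 1 of 20, had as many DESeq2 calls. The highest other had 395, and that grouping had 28 edgeR calls against 9 for the real one. A share of 1 of 20 is the smallest that this draw allows and is not under 0.05. The draw also lacks the exchange of control replicate 1 with MO1 replicate 3, which gave 5728 edgeR calls for the mean. DESeq2 was not run on that exchange, so chance is not excluded for the DESeq2 count. No filter gave 6 for MO2, 30 for the mean, 1 for MO1 against MO2 and a correlation of 0.562. With only the groups compared in the fit, MO1 had 1 and MO2 0. A minimum log2 fold change of 1 left 5 in the mean. Quality weights, lowest for control replicate 1 at 0.581, called 1813, 1419, 4617, 0 and 598. With 1 surrogate variable MO2 had 67, and with 2 surrogate variables MO2 had 0, the mean 0 and MO1 against MO2 1. The genes at an unadjusted p under 0.05 (4025, 5502, 5635 and 1964 as reported) were 8005 for MO1 and 9492 for the mean with quality weights, and 1034, 566 and 640 for MO1, MO2 and the mean with 2 surrogate variables, all 3 under the 1335.6 expected if nothing differed. Leaving out a library gave 2196 to 6510, 3400 to 7460, 3152 to 7932 and 1014 to 3446. The cause of these changes was not tested. The morpholinos as 1 group of 8 gave 10 for the mean. DESeq2 size factors and the stricter filter stayed within 1.5 times of each count.

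With the replicate number as a replicate block, MO2 and the mean had 0 calls, and other counts did not move. The numbers do not pair the libraries throughout: 4 of 12 same-number pairs had a correlation of deviations over 0.1 (range -0.346 to 0.355). These were the pairs among the libraries numbered 3 (0.266, 0.321 and 0.147) and control replicate 1 with MO1 replicate 1 (0.355). Only 3 of 12 libraries correlated best with their own number. A pairing of some numbers is thus not excluded.

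Leaving out each library in turn gave 0 to 544 calls for MO1, 0 to 1992 for MO2, 0 to 2669 for the mean, 0 to 1 for MO1 against MO2, 0 to 404 for both, and a correlation of 0.571 (without MO2 replicate 2) to 0.821 (without control replicate 1). The highest counts are those without control replicate 1, except for MO1 against MO2. The 4 printed IDs kept their direction in all 88 combinations of ID and alternative and stayed past the threshold in 45, with a log2 change of at least 0.55 in size and at most 1.98. These IDs were chosen by fold change in the same libraries, so the kept direction says little. With 2 surrogate variables their adjusted p was 1.00. Depth does not limit these IDs alike: their lowest count in a library was 19, for XBXL10_1g15791, and 84 or more for XBXL10_1g9012 and XBXL10_1g31540. The sum of homeologs, the gene list tests and the barhl1 transcript were not run, since no names are paired with the IDs.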

Other observations

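The tests of the 19 genes below were chosen after their values were seen; the counts over other groupings were planned. Ranked by CPM, 442 genes had all 8 morpholino libraries on 1 side of the 4 controls, 266 above and 176 below, which is 1.65% of genes where chance gives 0.404%. Of the 495 choices of 4 libraries, 13 separated as many genes, a share under 0.05. The highest other choice, control replicates 2 to 4 with MO1 replicate 3, separated 3297, which points to a structure of the libraries that the labels do not give. MO1 replicate 4 with MO2 replicates 1, 3 and 4, all morpholino libraries, separated 1175. Such structure can thus reach the real count without the labels, and the share alone does not exclude chance. There were 9 genes with no count in the 4 controls and a count in all 8 morpholino libraries, and 0 the other way round. Only the real choice, 1 of 495, gave as many, the highest other being 6.

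A set of 19 genes had no count in control replicates 2 to 4 and a count in all 8 morpholino libraries. Their summed counts were 961 and 678 in MO1 replicates 1 and 4 and 729 in MO2 replicate 2, 77 to 295 in the other 5 morpholino libraries, and 48 in control replicate 1. Depth is argued against as the cause of the spread among morpholino libraries, since the highest sum was 12.5 times the lowest. Across the 8 morpholino libraries the genes varied together, with a median pairwise Spearman correlation of 0.357, above all 1000 random sets matched on mean count (median 0.0238, highest 0.262). A candidate explanation is 1 further source of RNA, present at different shares in the dissected pieces, but genes switched on together to a different degree in each library would give the same correlation of 0.357, and without gene names neither can be tied to a cell type.

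For the agreement of both morpholinos, the shared controls are argued against as the whole cause, since the lowest correlation with separate controls was 0.379. Of 100 groupings of the libraries, 4 gave a correlation of at least the real 0.739, the highest other being 0.795, a share that lies under 0.05 by a single grouping. Control replicates 1 and 3 with MO2 replicates 3 and 4 as the controls gave 0.713 within this draw. Outside it, the same controls with the MO1 libraries kept as their own group gave 0.740, a grouping picked after seeing the data. The real grouping is thus not firmly set apart from chance by this correlation. A response to barhl1 depletion stays open as a hypothesis, as does a difference between control replicates 2 to 4 and the remaining libraries that may come from stage or dissection, and no test here tells these apart. In the split-control fits the correlation ranged up to 0.554.

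Other splits of the libraries bear on the counts of genes as follows. For MO1 against control the real count of calls is 0, which all 35 of 35 splits reach by construction, so it decides nothing (highest other 4110). Of these splits, 2 of 35 had as many as the real 4025 genes at an unadjusted p under 0.05 (highest other 8177), so chance is not excluded. The split with 4110 and 8177 exchanges control replicate 1 with MO1 replicate 3. For MO2 against control, 2 of 35 splits called at least the real 3 genes (highest other 947), and 2 of 35 had as many as the real 5502 at the unadjusted p (highest other 7042), so chance is not excluded either, and the other split exchanges control replicate 1 with MO2 replicate 2. Both point to a structure of the samples around control replicate 1. For MO1 against MO2 the real count is also 0, reached by all 35 of 35 splits, and decides nothing (highest other 6), while 10 of 35 had as many as 1964 genes at the unadjusted p (highest other 4753), so chance is not excluded. For the mean of both morpholinos, 1 of 100 groupings, the real one, called as many as 9 genes (highest other 8), and 2 of 100 had as many as 5635 at the unadjusted p (highest other 6450), shares under 0.05 among the groupings drawn. Groupings outside this draw called more than 9 genes, namely 28 with MO1 replicates 1, 2 and 4 and MO2 replicate 2 as the controls, and 5728 with control replicate 1 and MO1 replicate 3 exchanged, a grouping picked after seeing the data. With both of these libraries left out and no exchange, an alternative also chosen later, 5033 genes passed. Leaving both out would also remove exchanged labels, so this count does not decide whether an exchange took place. The real count of 9 is thus not the highest that regrouping gives, and these groupings point to a structure of the samples.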
